A study of Mus musculus with 20 samples.

How the data were processed

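The series holds bulk RNA-seq of polyA RNA from small intestine of mouse pups, in 4 groups of 5 libraries: pups of control dams and of dams with periodontitis, each at 2 and 7 weeks. The group, age and replicate number of each library were taken from the labels alone, which give no sex, litter, batch or segment of the intestine. The deposited values are RSEM expected counts per gene, stored as whole numbers. Per the submitters' processing notes, the authors trimmed reads with cutadapt 4.8, checked them with FastQC 0.11.8, aligned them with STAR 2.7.8a and counted them with RSEM 1.3.3. The notes list the builds GRCh38 and GRCm38 and state neither the annotation release nor the strandedness. The table has 55491 lines, of which 4 name no mouse gene and hold 0 counts. Of the gene IDs 55227 were matched to GENCODE M21 on GRCm38, from which all coordinates here come, and 264 were not matched. Symbols are those of the deposited table.

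Counts were analysed in R 4.3.3 with edgeR 4.0.16. Rounding changed 0 values. Genes were kept by filterByExpr with the 4 groups, which left 17464 genes and took away at most 0.08378% of a library's counts. Library sizes were scaled by TMM, and 1 mean per group was fitted to all 20 libraries by the robust quasi-likelihood method (16 residual degrees of freedom, common dispersion 0.0989). The contrasts were periodontitis against control at 2 weeks, the same at 7 weeks, the difference between these, and 7 against 2 weeks in control pups and in periodontitis pups. The p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Fold changes are on the log2 scale. Their standard error (SE) is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. It is thus worked back from the test and not read from the fitted coefficient. Log2 CPM of libraries use a prior count of 2. Where a group had at most 3 counts of a gene in all, the fold is given as a bound against a floor of 3 counts over the group.

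A set of 46 gene lists for cell types, segments and pathways was fixed before the data were examined, with 746 genes, of which 745 were found in the table. Lists with at least 5 tested genes were tested, 44 in all, which left out colon and mesothelium. The test was camera of limma 3.58.1 with a preset correlation of 0.01 between genes, two-sided, adjusted over the lists of 1 contrast. Each call was repeated with the correlation estimated from the data, and with fry. Per list, members were also counted past an adjusted p of 0.05 over the list alone, and the mean log2 CPM per library was compared between groups by an exact permutation test. All tests take the libraries of a group as independent, although the condition was that of the dams and litters are not given.

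The genes the text names follow a rule fixed at the same time. Among genes with an adjusted p under 0.05, a mean log2 CPM of at least 1 and a symbol that is not a predicted locus, the 10 largest rises and 10 largest falls are named, or 5 and 5 for age in periodontitis pups and for the difference between ages. Where fewer than 10 genes pass, the 10 smallest p are named as well. Up to 4 members with the smallest p are named per described list, and a fixed set of genes of intestinal immunity and digestion is always given; 2 genes the rule names are not reported here. Single-library values were chosen for display after they were seen, as was Sprr2a1.

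The procedure was tested on simulated data. Genes set to change by 1.5, 2 and 4 times at 2 weeks were recovered in 11.9%, 58.2% and 92.4% of cases, with 3 false calls among 17173 genes. At 7 weeks the shares were 10.4%, 47.8% and 97%, with 5 false calls among 17168 genes. A shifted list of 25 genes was called each time and 0 of 43 random lists were. The simulated genes varied independently of each other. This therefore does not test how often camera falsely calls lists whose genes vary together. Changes of 1.5 times were mostly missed in the simulation at this depth and n. Its 200 changes were set only in genes above a low level of expression, and no simulated library was made to stand apart. The shares recovered are thus not those of the real data. There, Cfd (21.4-fold) and Retn (22.3-fold) at 7 weeks did not pass (edgeR adjusted p = 0.1 each).

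Alternatives were DESeq2 1.42.0, its size factors in edgeR, limma-voom with sample quality weights, no filter and a filter of CPM above 1 in 5 libraries, fits to the compared groups alone, no robust estimation, the replicate number as a block, covariates for Y-linked transcripts and for segment, removal of pancreatic, plasma cell, erythroid and immunoglobulin genes, and removal of each library in turn. Added after the data were seen were the removal of 2 libraries together, removal of mitochondrial genes, and covariates for enterocyte maturity, for adipocyte genes and for the proximal and distal lists each with its own score. Erythroid genes were not called between dams (median 0.43 at 2 weeks, camera adjusted p = 0.653). Reads, splicing and transcripts below gene level were not analysed here.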

Results

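Small intestine was collected from mouse pups of control dams and of dams with periodontitis, the inflammation of the tissue that anchors the teeth. Its polyA RNA was sequenced in bulk. The pups were 2 or 7 weeks old, so the 20 libraries fell into 4 groups of 5. The stated purpose was to compare gene expression between the 2 kinds of dam, in a study of maternal oral bacteria and intestinal inflammation in offspring. Total counts ran from 14.9 to 42.6 mega counts (M) per library. The group means were 30.8 ± 9.38 M in control pups at 2 weeks, 37.2 ± 4.21 M in periodontitis pups at 2 weeks, 33.9 ± 3.22 M in control pups at 7 weeks and 31.2 ± 6.73 M in periodontitis pups at 7 weeks (SD, n = 5 each). Below, "periodontitis pups" are pups of dams with periodontitis. A log2 fold change is periodontitis against control or 7 against 2 weeks. CPM are deposited counts per M counts scaled by trimmed mean of M values (TMM).

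**Figure D1:**
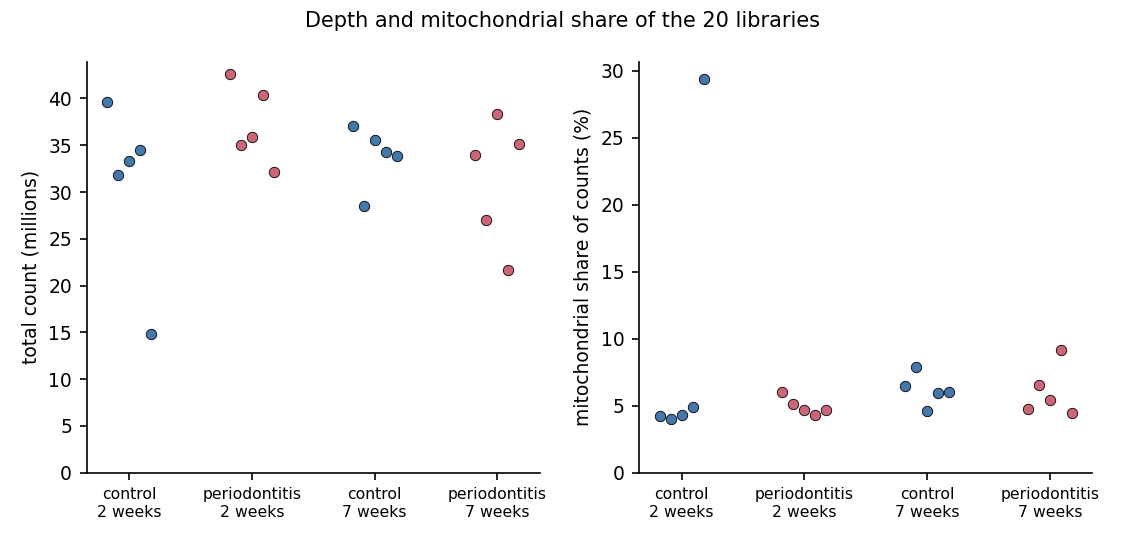
Total count in M (left panel) and mitochondrial share of counts in percent (right panel) for the 20 libraries, 1 point per library in order of replicate number, 5 per group. Control library 5 at 2 weeks had 14.88 M counts and a mitochondrial share of 29.41%, against 3.99% to 4.87% in the other control libraries of that age.

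Age was the main axis of the data. The first principal component held 67.3% of the variance and parted the 2-week from the 7-week libraries. The next held 12.6%. Apoa4, the apolipoprotein of enterocyte lipid particles, was the most abundant gene in 19 of the 20 libraries. In control library 5 at 2 weeks it was mt-Co1, a mitochondrially encoded subunit of cytochrome oxidase, at 5.751% of counts. That library held counts for 20080 genes, against 23350 to 23574 in the other control libraries of its age. Periodontitis library 5 at 7 weeks also stood apart, with Apoa4 at 2.119% of counts against 4.648% to 5.574% in the other libraries of its group. Transcripts of the X-inactivation gene Xist and of Y-linked genes differed between the ages. All 10 libraries of 7 weeks had Ddx3y, a Y-linked helicase gene, at 29.2 to 152 CPM and Xist at no more than 0.658 CPM. At 2 weeks, control library 1 had Xist at 92.3 CPM and 0 counts of Ddx3y, and periodontitis library 1 had 131 CPM of Xist and 2 counts of Ddx3y. Periodontitis library 4 had 137 CPM of Xist and 0.716 CPM of Ddx3y, and periodontitis library 3 had 0.71 and 35 CPM. The other 6 libraries of that age carried both transcripts. Control library 3, for example, had Xist at 90 CPM and Ddx3y at 16.5 CPM. The labels give neither the sex nor the number of pups per library.

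At 2 weeks, the age of suckling, genes of the suckling enterocyte were higher in periodontitis pups and genes of the weaned enterocyte were lower. The 16 suckling enterocyte genes, many of which serve the uptake of milk proteins or lysosomal digestion, had a median log2 fold change of 0.91, and 14 of the 16 were higher. Lrp2, the endocytic receptor megalin, differed by 2.24 ± 0.48 (SE, n = 5 per group). Fcgrt, the neonatal receptor that carries maternal IgG across the epithelium, differed by 1.99 ± 0.47, the lysosomal sialidase Neu1 by 0.98 ± 0.23 and the lysosomal protease Ctsz by 0.78 ± 0.17. All 8 weaned enterocyte genes were lower, with a median log2 fold change of -0.86. Slc5a1, the sodium-coupled glucose transporter, differed by -1.02 ± 0.21, the maltase gene Mgam by -1.52 ± 0.39, sucrase-isomaltase (Sis) by -2.33 ± 0.72 and arginase 2 (Arg2) by -1.28 ± 0.53.

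Adjusted over the list alone, 12 of the 16 suckling enterocyte genes rose and 3 of the 8 weaned enterocyte genes fell (Slc5a1, Mgam and Sis). Adjusted over all 17464 genes tested, 0 of either list passed in edgeR. Against all other genes, camera gave the suckling list an adjusted p of 2.15e-10 and the weaned list 1.48e-06. These became adjusted p = 0.149 and adjusted p = 0.166 with an estimated correlation. The fry test, which tests the direction of the list itself, gave adjusted p = 0.00825 and adjusted p = 0.0233. Per library, the mean log2 CPM of the suckling list was 6.27 ± 0.56 in control pups and 7.24 ± 0.3 in periodontitis pups (SD, n = 5, exact permutation p = 0.0159, two-sided; adjusted over 44 lists 0.175). For the weaned list it was 8.37 ± 0.16 and 7.09 ± 1 (SD, n = 5, exact permutation p = 0.0238, two-sided, adjusted 0.209). Both tests take the libraries of a group as independent, and the labels do not say which pups shared a litter. The periodontitis libraries were not alike: weaned list means were 8.02 and 8.26 in libraries 1 and 2, and 6.73, 5.97 and 6.46 in libraries 3, 4 and 5. Sis stood at 277 and 462 CPM in the former and at 28, 9 and 19.2 CPM in the latter, against 544 to 1500 CPM in the control libraries. Fcgrt ran the other way, at 1440 and 951 CPM in libraries 1 and 2, at 3290, 3110 and 4050 CPM in libraries 3, 4 and 5, and at 76 to 1000 CPM in the control libraries, of which library 5 had the 76. Fabp6, the bile acid binding protein of the ileum, was at 365, 328, 17.5, 2.92 and 8.07 CPM in periodontitis libraries 1 to 5. In the control libraries it was at 197 to 510 CPM. The mean log2 CPM of the distal intestine list was 4.55, 4.07 and 4.16 in periodontitis libraries 3, 4 and 5 against 5.66 to 6.44 in the controls, and that of the proximal list 7.63, 7.15 and 7.72 against 8.27 to 8.52. The distal list was not called (median -0.39, camera adjusted p = 0.267).

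**Figure D2:**
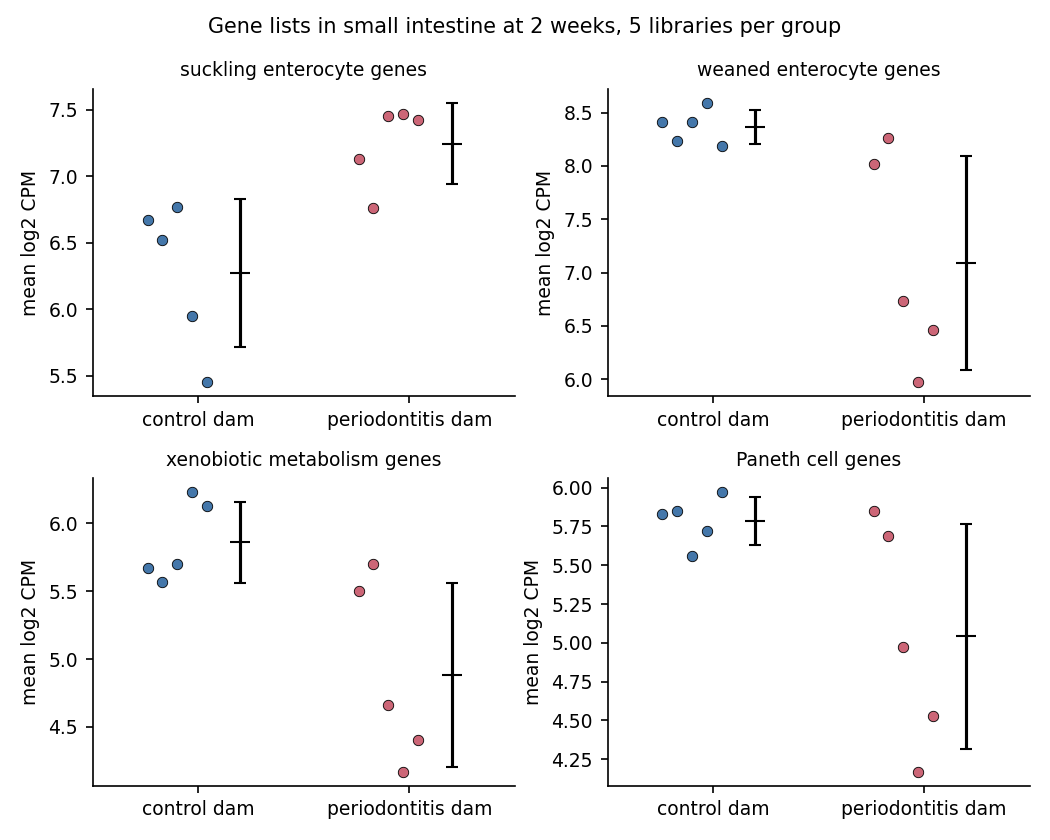
Mean log2 CPM of 4 gene lists (vertical axes) in the 10 libraries of 2 weeks, 1 point per library in order of replicate number, with mean and SD beside each group of 5; the vertical axes do not start at 0. Suckling enterocyte means were 5.45 to 6.77 in control and 6.76 to 7.47 in periodontitis pups, and in the other 3 lists periodontitis libraries 3, 4 and 5 lay below all control libraries.

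Genes for the metabolism of foreign compounds were lower in periodontitis pups at 2 weeks, with a median log2 fold change of -0.81 over 25 genes, 22 of them negative. Aldh1a1, which makes retinoic acid from retinal, differed by -1.39 ± 0.29 (SE, n = 5 per group). Cyp1a1, the classic target of the aryl hydrocarbon receptor, differed by -4.33 ± 1.17, and the glutathione transferases Gstm3 and Gsta1 by -1.55 ± 0.44 and -1.37 ± 0.39. Cyp1a1 was low in both groups, at 0.659 ± 0.866 and 0.024 ± 0.033 CPM (SD, n = 5). Adjusted over the list alone 11 of the 25 fell, and 0 did over all genes. Camera gave the list adjusted p = 4.95e-12 (adjusted p = 0.149 with an estimated correlation) and fry adjusted p = 0.0189.

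Paneth cell genes, the defensins and lysozyme of the crypt base, had a median of -0.62, with 18 of 19 negative and 0 past the threshold over the list alone or over all genes. Defa5 differed by -1.25 ± 0.45 and Defa29 by -1.49 ± 0.71. The mean log2 CPM of the Paneth list was 5.85 and 5.69 in periodontitis libraries 1 and 2, within the 5.56 to 5.97 of the controls. It was 4.97, 4.17 and 4.53 in libraries 3, 4 and 5. Camera gave adjusted p = 5.82e-06 (adjusted p = 0.719 with an estimated correlation). The list of antimicrobial proteins had a median of -0.62, with 16 of 17 negative. Its mean log2 CPM was 4.88 and 4.47 in periodontitis libraries 1 and 2, against 4.52 to 4.99 in the controls. In libraries 3, 4 and 5 it was 3.24, 3.18 and 3.47. Over the list alone 5 fell: the C-type lectin Reg3a (-1.95 ± 0.58), Sprr1a (-1.44 ± 0.49), the tryptophan-degrading enzyme Ido1 (-1.79 ± 0.62), the goblet cell lectin Zg16 (-1.02 ± 0.37) and Sprr2a1 (-1.03 ± 0.38). Over all genes 0 did. Camera gave adjusted p = 1.06e-05 (adjusted p = 0.383 with an estimated correlation). Nuclear genes of oxidative phosphorylation had a median of -0.24 with 23 of 24 negative (camera adjusted p = 0.000568, and adjusted p = 0.712 with an estimated correlation), and 0 passed over the list alone. The median was -0.16 without periodontitis library 4. This list was also low in control library 5, the library with the high mitochondrial share, at a mean log2 CPM of 7.32 against 7.72 to 7.85 in the other controls.

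Genes most abundant in liver were higher in periodontitis pups at 2 weeks, with a median of 1.51 over 7 genes. Per library the mean log2 CPM was 1.28 ± 0.43 in control and 2.43 ± 0.29 in periodontitis pups, without overlap (SD, n = 5, exact permutation p = 0.00794, two-sided; adjusted 0.116). Over the list alone 4 rose: the protease inhibitor Serpina1a (2.36 ± 0.5), the fibrinogen chains Fga (2.3 ± 0.43) and Fgb (2.06 ± 0.44) and the thyroid hormone carrier Ttr (1.51 ± 0.39). Over all genes 0 did. Their levels were low, with Fga at 0.917 ± 0.492 CPM in control and 4.65 ± 1.6 CPM in periodontitis pups (SD, n = 5). Albumin, the most abundant liver transcript, was too low to be tested. Camera gave adjusted p = 2.98e-05 (adjusted p = 0.0532 with an estimated correlation) and fry adjusted p = 0.000143. Camera also called goblet cell genes (median -0.17, adjusted p = 0.00839, and adjusted p = 0.719 with an estimated correlation), genes of the proximal intestine (-0.14, adjusted p = 0.0315, and adjusted p = 0.503 with an estimated correlation) and proliferation genes (-0.19, adjusted p = 0.0485, and adjusted p = 0.956 with an estimated correlation). The goblet call was lost without control library 4 (adjusted p = 0.0635), and its median was -0.29 without periodontitis library 1. The proximal call was lost without control library 1, 3 or 4 or periodontitis library 4, and the proliferation call without control library 2, 4 or 5 or periodontitis library 4 or 5, with adjusted p up to 0.152 and 0.174 in camera. The proximal median ran from -0.26 to -0.05 over single left-out libraries, and the proliferation median was -0.12 without control library 5. The other 7 list calls held on leaving out each of the 10 libraries in turn. With a covariate for enterocyte maturity, built from the suckling and weaned lists, calls were lost for weaned enterocyte (camera adjusted p = 0.251), foreign compound (0.458), Paneth cell (0.458), antimicrobial (0.0654), proximal (0.111) and proliferation genes (0.374). Goblet cell and oxidative phosphorylation genes were then called higher (median 0.14, adjusted p = 0.0202, and 0.1, adjusted p = 0.0374). This covariate ran from -1.77 to -0.677 in control and from -0.527 to 2.47 in periodontitis libraries, without overlap. Since it parts the groups, lost calls and changed signs in this fit decide nothing. With the proximal and the distal score as 2 covariates, calls were lost for Paneth cell, goblet cell, oxidative phosphorylation, proximal and proliferation genes (adjusted p from 0.309 to 0.704). The suckling and weaned medians were then 0.58 and -0.47 and were still called (adjusted p = 8.6e-08 and 8.3e-05). The proximal score is the mean of the proximal list, so the loss of the proximal call was fixed in advance. Both scores were lower in periodontitis libraries 3, 4 and 5, so this fit also takes away what else sets these apart. The other lost calls therefore decide little. In all, camera called 10 of the 44 lists at 2 weeks, 2 up and 8 down. With an estimated correlation 0 held, and fry called 4 (suckling and weaned enterocyte, metabolism of foreign compounds, liver).

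Single genes passed in small number. EdgeR called 5 of the 17464 genes at an adjusted p under 0.05, 3 higher and 2 lower. There were 2511 at an unadjusted p under 0.05 against 873 expected by chance. C8b (ENSMUSG00000029656, chromosome 4, 104766317 to 104804548 on GRCm38), which encodes the beta chain of complement component C8, rose by a log2 fold change of 3.86 ± 0.63 (SE, n = 5 per group), from 0.663 ± 0.35 to 9.82 ± 7.51 CPM (SD). Ifit2 (ENSMUSG00000045932, chromosome 19, 34550694 to 34576419), an interferon-induced gene, rose by 2.19 ± 0.37, and Mfsd2a (ENSMUSG00000028655, chromosome 4, 122946850 to 122961188), a lysophospholipid transporter, by 1.67 ± 0.29. Maoa (ENSMUSG00000025037, chromosome X, 16619698 to 16687818), which encodes monoamine oxidase A, differed by -1.73 ± 0.28, from 65.7 ± 26.5 to 19.7 ± 10.4 CPM. Trim38 (ENSMUSG00000064140, chromosome 13, 23769913 to 23791528), a regulator of innate immune signalling, differed by -2.52 ± 0.44. Each of the 5 had an edgeR adjusted p of 0.043. Each lay beyond the range of all 5 control libraries in every periodontitis library. C8b stood at 14.8, 11.1 and 18.8 CPM in periodontitis libraries 3, 4 and 5, at 2.9 and 1.45 CPM in libraries 1 and 2, and at 0.154 to 1.11 CPM in the controls. The next genes by p did not pass, at an adjusted p of 0.054: Sowaha (-0.89 ± 0.16), 9530053A07Rik (1.72 ± 0.32), the near-identical pseudogenes Gm3089 and Gm3302 (1.86 ± 0.35 each) and the lysosomal protease Ctsl (1.71 ± 0.32). Without control library 5, whose mitochondrial share was high, edgeR called 49 genes, and without that library and periodontitis library 5 of 7 weeks, 361.

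The count at 2 weeks moved with the tool, with covariates and with single libraries. DESeq2 called 599 genes (41.4% higher, against 60% of the 5 in edgeR), and limma-voom with sample quality weights 5170. Those weights were 4.82 for periodontitis library 3 and 3.12 to 3.3 for control libraries 1 to 3. They were 0.624 and 0.709 for periodontitis libraries 1 and 2, and 0.0402 to 1.65 over all the rest of that age. The weighted count thus leaned on few libraries. The count was 0 for edgeR with DESeq2's size factors (2628 at an unadjusted p under 0.05), for edgeR with a covariate for the Y-linked transcripts (2028) and for edgeR fitted to the 2-week groups alone (2159). It was 17 without robust estimation and 40 with the segment covariate. It was 0 with the proximal and the distal score as 2 covariates (705) and 0 with the maturity covariate (113), whose values did not overlap between the groups. With the latter, C8b was at 0.68, Ifit2 at 0.44, Mfsd2a at 0.79, Maoa at -0.67 and Trim38 at -0.77, and with the former at 2.18, 1.07, 0.88, -1.22 and -1.77. With 1 library left out, edgeR called 96 genes without periodontitis library 1, and 387 without periodontitis library 2. It called 0 (1660 to 2833 at an unadjusted p under 0.05) without any of control libraries 1 to 4 or periodontitis libraries 3 to 5.

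Of the genes fixed beforehand for their role in intestinal immunity and digestion, 0 passed at 2 weeks in edgeR. The Th17 cytokine genes Il17a and Il22 were too low to be tested, with 0 and 1 counts over the 10 libraries of 2 weeks and 2 counts each at 7 weeks. Of the inflammatory cytokines, Il1b differed by -0.11 ± 0.35 and Tnf by 0.35 ± 0.45 (SE, n = 5 per group). The bactericidal lectins Reg3b and Reg3g differed by -0.61 ± 0.63 and -1.35 ± 0.73, the Paneth cell lysozyme Lyz1 by -0.95 ± 0.64, the mucin Muc2 by -0.14 ± 0.27 and the stem cell receptor Lgr5 by -0.32 ± 0.36. Lactase (Lct), which digests milk sugar, differed by 0.1 ± 0.24, in contrast to most of the suckling list. The antibody genes Jchain and Igha differed by -1.04 ± 0.59 and -0.37 ± 0.85. Fcgrt and Sis had adjusted p of 0.064 and 0.14. In the list of inflammatory cytokines, adjusted over the list alone, the alarmin Il33 (-1.33 ± 0.28), the chemokine Ccl20 (-1.82 ± 0.59) and Il18 (-1 ± 0.32) fell and Il1a (1.02 ± 0.36) rose. Over all genes 0 passed. The list as a whole was not called (median -0.28, camera adjusted p = 0.145). In the list of interferon-stimulated genes, Ifit2 and the nucleic acid sensor Zbp1 (1.1 ± 0.29) rose over the list alone, and the list was not called (median 0.1, camera adjusted p = 0.0643). Its mean log2 CPM per library was 4.39 ± 0.1 in control and 4.69 ± 0.15 in periodontitis pups, without overlap (SD, n = 5, exact permutation p = 0.00794, two-sided; adjusted 0.116). So it was for endothelial genes, at 4.07 ± 0.09 and 4.39 ± 0.05 with the same p.

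At 7 weeks, after weaning, genes of B cells were on average lower in periodontitis pups, with overlap between libraries. Adjusted over all genes tested, no B cell gene passed in edgeR (adjusted p = 0.22 for Fcmr and 0.31 for Pax5). Scd1, Klf15 and some genes of fat cells were higher. All 17 B cell genes were lower, with a median log2 fold change of -2.27. The IgM receptor gene Fcmr differed by -4.04 ± 0.88 (SE, n = 5 per group), Pax5, the transcription factor of B cell identity, by -4.12 ± 0.97, the inhibitory receptor Cd22 by -1.81 ± 0.47 and the complement receptor Cr2 by -2.87 ± 0.81. Scd1, the desaturase that makes monounsaturated fatty acids, stood at 5.77 ± 0.852 CPM in control and 21.5 ± 11.7 CPM in periodontitis pups (SD, n = 5). Klf15, a transcription factor of fasting and glucocorticoid metabolism, stood at 3.42 ± 0.788 and 14.1 ± 8.04 CPM. The adipocyte genes Cfd, Retn and Adipoq, which encode the secreted proteins adipsin, resistin and adiponectin, had log2 fold changes of 4.42 ± 0.81, 4.48 ± 0.82 and 4.66 ± 0.97.

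EdgeR called 2 of 17464 genes at 7 weeks. There were 582 at an unadjusted p under 0.05 against 873 expected by chance. Scd1 (ENSMUSG00000037071, chromosome 19, 44394455 to 44407879 on GRCm38) rose by 1.9 ± 0.28 and Klf15 (ENSMUSG00000030087, chromosome 6, 90462576 to 90475238) by 2.05 ± 0.31 (SE, n = 5 per group), both with an edgeR adjusted p of 0.019. Both were higher in each of the 5 periodontitis libraries than in any control library. The next genes by p did not pass: Cfd and Retn (adjusted p = 0.1), Gpr183, a receptor that guides B cells (-1.87 ± 0.36, adjusted p = 0.14), and the carbonic anhydrase Car3 of fat and muscle (2.92 ± 0.58, adjusted p = 0.18). Nor did the T cell costimulator Icos (-2.06 ± 0.42, edgeR adjusted p = 0.19). Adipoq, the cell cycle kinase Wee1 (-0.62 ± 0.13) and the growth factor binding protein Fgfbp3 (1.13 ± 0.24) were at an edgeR adjusted p of 0.2. Without periodontitis library 5, which stood apart from its group, edgeR called 15 genes, and without it and control library 5 of 2 weeks, 32. Without periodontitis library 4 it called 5. Without any 1 of the 5 control libraries it called 0 (492 to 675 at an unadjusted p under 0.05). DESeq2 called 25 genes (48% higher, against 100% in edgeR), and limma-voom with sample quality weights 10. EdgeR fitted to the 7-week groups alone called 0 (383 at an unadjusted p under 0.05), and edgeR with the adipocyte genes as a covariate 0 (1216).

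Adjusted over the list alone, 14 of the 17 B cell genes fell, and over all genes 0 did. Camera gave adjusted p = 9.05e-23 (adjusted p = 0.248 with an estimated correlation) and fry adjusted p = 0.638. The libraries overlapped. The mean log2 CPM of the list was 1.12, 0.8, 2.36, 0.83 and -1.73 in control libraries 1 to 5 and -1.67, -2.01, -2.03, 0.6 and -1.09 in periodontitis libraries 1 to 5. The group means were 0.68 ± 1.49 and -1.24 ± 1.1 (SD, n = 5, exact permutation p = 0.0556, two-sided; adjusted over 44 lists 0.612). Plasma cell genes had a median of -1.03 with 12 of 13 negative. Over the list alone 3 fell, the antibody chains Iglc1 (-1.88 ± 0.42), Iglc2 (-2.14 ± 0.51) and Ighm (-1.4 ± 0.35), and over all genes 0 did. Camera gave adjusted p = 1.72e-08 (adjusted p = 0.354 with an estimated correlation). The genes of MHC class II, which presents antigen to helper T cells, had a median of -0.61 with all 11 negative. Over the list alone 3 fell, H2-Eb2 (-2.54 ± 0.57), H2-DMb2 (-1.56 ± 0.46) and H2-Ob (-1.51 ± 0.47), and over all genes 0 did (camera adjusted p = 1.4e-06, and adjusted p = 0.367 with an estimated correlation). Macrophage and dendritic cell genes had a median of -0.48, with the lymph node homing receptor Ccr7 at -2.51 ± 0.74 and 0 genes past the list-alone threshold (camera adjusted p = 1.89e-05, and adjusted p = 0.482 with an estimated correlation). T cell genes had a median of -0.21, with Icos past the list-alone threshold (camera adjusted p = 0.000382, and adjusted p = 0.662 with an estimated correlation). This call was lost without control library 3 or periodontitis library 4 or 5, with adjusted p up to 0.126, and without control library 3 the median was 0.08. The medians of the other 4 lists were also smaller without control library 3, at -1.5 for B cells, -0.14 for plasma cells, -0.09 for MHC class II and -0.17 for macrophages and dendritic cells, and camera still called them (adjusted p up to 0.0163). Without periodontitis library 5 the plasma cell median was -1.66 and that of macrophages and dendritic cells -0.96. With the adipocyte genes as a covariate the B cell call held (adjusted p = 1.69e-05), and those of plasma cells, MHC class II and macrophages and dendritic cells were lost (0.732, 0.192 and 0.87). This covariate was higher in periodontitis libraries 1 to 4 than in any control library, so lost calls in this fit, here and below, decide little.

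Adipocyte genes had a median of 0.72 at 7 weeks (0.42 without periodontitis library 4), and over the list alone 4 of 9 rose: Cfd, Retn, Adipoq and the lipid droplet coat gene Plin1 (3.05 ± 0.87). Over all genes 0 did. Camera gave adjusted p = 0.000139 (adjusted p = 0.354 with an estimated correlation) and fry adjusted p = 0.642. Cfd stood at 14.8, 10.4, 9.49, 39.4 and 0.174 CPM in periodontitis libraries 1 to 5 and at 0.389 to 1.09 CPM in the controls, so library 5 did not share the higher level. Scd1 stood at 10.8, 11.3, 38, 28.5 and 18.9 CPM and Klf15 at 9.4, 7.21, 26.8, 9.78 and 17.1 CPM in the same libraries. Cholesterol synthesis genes had a median of -0.15 with 20 of 22 negative. Over the list alone Insig1, the sterol sensor that holds back this pathway, fell (-0.82 ± 0.18), and over all genes 0 did (camera adjusted p = 5.8e-06, and adjusted p = 0.354 with an estimated correlation). The cholesterol median was -0.27 without periodontitis library 1. In the list of antimicrobial proteins, which was not called (median 0.38, camera adjusted p = 0.245), the epithelial oxidase Duox2 (3.52 ± 0.77) and its maturation factor Duoxa2 (3.36 ± 0.78) rose over the list alone, and over all genes 0 did. Duox2 stood at 9.87, 37.8, 3.57, 39 and 0.463 CPM in periodontitis libraries 1 to 5 and at 0.778 to 3.05 CPM in the controls.

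**Figure D3:**
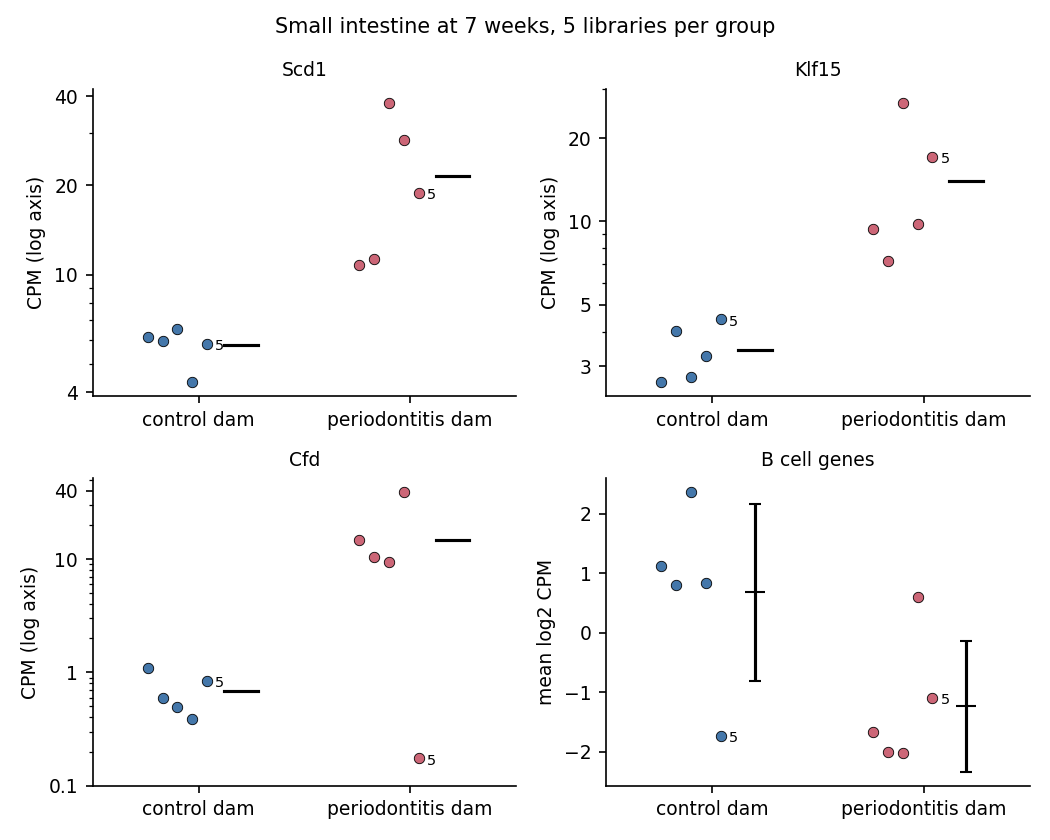
CPM of Scd1, Klf15 and Cfd (log axes) and mean log2 CPM of 17 B cell genes in the 10 libraries of 7 weeks, 1 point per library in order of replicate number; bars are group means, with SD for the B cell genes, and library 5 of each group is marked. Scd1 and Klf15 are higher in all 5 periodontitis libraries than in any control library, Cfd in all but library 5, and the B cell values of the groups overlap.

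Camera called 13 of the 44 lists at 7 weeks, 3 up and 10 down. Of these, 0 held with an estimated correlation or passed in fry. The remaining calls were enteric nervous system genes (median 0.6, adjusted p = 0.0301, and adjusted p = 0.894 with an estimated correlation) and mast cell genes (0.34, adjusted p = 0.0101, and adjusted p = 0.354 with an estimated correlation). Immediate early and heat shock genes (-0.18, adjusted p = 0.0206, and adjusted p = 0.701 with an estimated correlation), metabolism of foreign compounds (-0.15, adjusted p = 0.0206, and adjusted p = 0.806 with an estimated correlation), proximal intestine genes (-0.06, adjusted p = 0.0141, and adjusted p = 0.354 with an estimated correlation) and genes induced by interferon gamma (adjusted p = 0.0474, and adjusted p = 0.8 with an estimated correlation) were called too. The last list was called down by camera with a mean of -0.11 while its median was 0.01, and the median ran from -0.31 to 0.09 over single left-out libraries. All of these 6 calls were lost on leaving out 1 library. Enteric nervous system and immediate early genes were lost without control library 2 or 4 or periodontitis library 5 (adjusted p up to 0.968 and 0.922). Without periodontitis library 5 the enteric nervous system median was 0.12 and the immediate early median 0. Mast cell genes were lost without periodontitis library 5 (0.174) and proximal genes without control library 4 (0.056). The proximal median ran from -0.33 to 0 over single left-out libraries. Metabolism of foreign compounds was lost without control library 2 or 5 or periodontitis library 2, 4 or 5 (up to 0.186, median -0.09 without control library 5), and interferon gamma genes without control library 1, 3 or 4 or periodontitis library 3, 4 or 5 (up to 0.91). With the adipocyte genes as a covariate mast cell, proximal and foreign compound genes were not called (0.0903, 0.804 and 0.87). With the segment covariate the medians were -0.44 for immediate early, -0.36 for foreign compound and -0.18 for proximal genes. The suckling and weaned enterocyte lists had medians of 0.07 and -0.04 and were not called (camera adjusted p = 0.407 and 0.245).

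Of the genes fixed beforehand, 0 passed at 7 weeks in edgeR, each with an adjusted p of 1. Reg3b differed by 1.66 ± 0.64 and Reg3g by 0.6 ± 0.71 (SE, n = 5 per group), Lyz1 by 0.22 ± 0.63, Muc2 by 0.02 ± 0.27, Lgr5 by -0.04 ± 0.38, Sis by -0.08 ± 0.69, Lct by -0.06 ± 0.24 and Fcgrt by -0.02 ± 0.45. Il1b differed by -0.59 ± 0.37, Tnf by -0.24 ± 0.54, Jchain by -0.29 ± 0.56 and Igha by -1.03 ± 0.85.

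The difference between dams was itself compared between the ages. EdgeR called 4 genes, all with a higher log2 fold change at 7 than at 2 weeks, with 1537 at an unadjusted p under 0.05. They were Klf15 (difference 3.16 ± 0.44, SE, adjusted p = 0.01), Cfd (7.47 ± 1.12, adjusted p = 0.016; ENSMUSG00000061780, chromosome 10, 79890853 to 79892655), Scd1 (2.41 ± 0.39, adjusted p = 0.024) and Retn (7.05 ± 1.15, adjusted p = 0.024; ENSMUSG00000012705, chromosome 8, 3655770 to 3660110). Cfd was lower in periodontitis pups at 2 weeks (0.269 ± 0.128 against 2.19 ± 1.39 CPM, SD, n = 5) and higher at 7 weeks (14.8 ± 14.7 against 0.682 ± 0.286 CPM). The next genes by p did not pass: Adipoq (6.72 ± 1.29), Mfsd2a (-2.07 ± 0.4), Car3 (3.94 ± 0.78) and the haptoglobin gene Hp (5.13 ± 1.01) at an adjusted p of 0.13. The glutamate dehydrogenase gene Glud1 (1.3 ± 0.27) and Maoa (1.91 ± 0.39) were at 0.15. Camera called 13 lists, and with an estimated correlation or in fry 0. Suckling enterocyte genes had a median difference of -0.77 (adjusted p = 2.87e-06, and adjusted p = 0.542 with an estimated correlation), weaned enterocyte genes 0.98 (adjusted p = 0.00205, and adjusted p = 0.565 with an estimated correlation) and B cell genes -2.26 (adjusted p = 2.32e-07, and adjusted p = 0.565 with an estimated correlation). Antimicrobial proteins had a median difference of 1.1 (adjusted p = 3.62e-06, and adjusted p = 0.542 with an estimated correlation) and Paneth cell genes 0.89 (adjusted p = 6.84e-05, and adjusted p = 0.724 with an estimated correlation). Without periodontitis library 5 of 7 weeks the Paneth value was -0.04 and was not called (adjusted p = 0.0859), and without control library 1 of 7 weeks it was 1.56. The gene calls at the 2 ages had 0 genes in common. The log2 fold changes of the ages had a Pearson r of -0.049 across 17464 genes, which are not independent replicates.

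That count of 4 was 9 without control library 5 of 2 weeks, 26 without periodontitis library 5 of 7 weeks and 159 without both. DESeq2 called 65 genes (64.6% higher, against 100% in edgeR) and limma-voom with sample quality weights 1166 (66.2% higher). The edgeR count was 14 without periodontitis library 2 of 2 weeks. It was 1 or 2 without any of control libraries 1 to 5 or periodontitis library 4 of 7 weeks, or control libraries 1, 2 and 4 or periodontitis libraries 1, 3, 4 and 5 of 2 weeks. With the segment of intestine as a covariate it was 1.

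The intestinal tissue taken from control pups differed widely between 2 and 7 weeks. The labels do not give the stretch of intestine taken at either age, so the values with age compare the pieces as taken. Genes for the metabolism of foreign compounds rose by a median log2 fold change of 2.45, with 22 of 25 up and 1 down. Among them were the glutathione transferase Gstm1 (4.53 ± 0.3, SE, n = 5 per group), Cyp1a1 (8.71 ± 0.86), Cyp3a11 (4.35 ± 0.46) and Cyp2c66 (4.47 ± 0.49). All 8 weaned enterocyte genes rose (median 2.35). Among these were the fructose transporter Slc2a5 (4.9 ± 0.38), the fructose enzyme Khk (2.91 ± 0.38) and trehalase, Treh (3 ± 0.41). Genes of the matrix-forming fibroblast fell in 18 of 18 cases (median -3.03), among them Mfap5 (-3.66 ± 0.26), Postn (-4.35 ± 0.42), Sparc (-2.94 ± 0.29) and Col3a1 (-2.85 ± 0.28). Proliferation genes fell in 24 of 25 cases (median -1.67), among them Nusap1 (-1.96 ± 0.3) and the replication helicase subunit Mcm4 (-1.42 ± 0.24). EdgeR called 10739 of 17464 genes, 4740 higher and 5999 lower at 7 weeks.

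Genes of plasma cells, cytotoxic lymphocytes and T cells were higher at 7 weeks. Plasma cell genes had a median of 3.83, with 10 of 13 up and 1 down. The light chains Iglc1 and Iglc2 rose by 7.83 ± 0.58 and 6.34 ± 0.63 and Iglv1 by 7.87 ± 0.98. Jchain, which joins secreted IgA, rose by 6.65 ± 0.72, and Igha by 6.05 ± 1.05. Cytotoxic lymphocyte genes had a median of 2.69, with 12 of 15 up and 1 down. The chemokine Ccl5 rose by 6.02 ± 0.43, the granzymes Gzma and Gzmb by 5.14 ± 0.37 and 5.13 ± 0.45, and Cd8a by 3.7 ± 0.34. T cell genes (median 1.37, 11 of 18 up, Cd3g 3.45 ± 0.32), genes induced by interferon gamma (0.99, 14 of 25 up and 1 down, Psmb9 2.29 ± 0.19) and interferon-stimulated genes (0.62, 15 of 28 up and 1 down, Oasl1 2.11 ± 0.29) rose as well. Camera gave these 5 lists adjusted p of 0.000762, 6.26e-06, 0.00122, 0.000762 and 0.000762. With an estimated correlation they had adjusted p = 0.423, adjusted p = 0.318, adjusted p = 0.428, adjusted p = 0.318 and adjusted p = 0.538. B cell genes were not called (median 0.24, camera adjusted p = 0.704). Nor were neutrophil (-0.89, camera adjusted p = 0.19), innate sensing (-0.7, 0.263), macrophage and dendritic cell (-0.46, 0.263) and mast cell genes (-1.21, and -1.15 at the floor of 3 counts, 0.114), all with negative medians. Of these 4, fry called neutrophil (adjusted p = 0.00238), innate sensing (0.00152) and mast cell genes (2.07e-05). Lipid absorption genes rose in 15 of 21 cases (median 1.28, Fabp1 2.47 ± 0.19), with 1 down, and oxidative phosphorylation genes in 19 of 24 (median 0.97, Ndufa1 1.82 ± 0.16). Their camera adjusted p were 3.03e-05 and 5.81e-07, with adjusted p = 0.334 and adjusted p = 0.318 with an estimated correlation. Tuft cell genes (median 1.06, 11 of 15 up and 2 down, Trpm5 2.4 ± 0.32), barrier junction genes (0.69, 14 of 20 up and 4 down, Cldn15 2.42 ± 0.31) and immediate early and heat shock genes (1.31, 11 of 15 up, Jun 1.75 ± 0.26) had camera adjusted p of 0.00444, 0.0157 and 0.00185, with adjusted p = 0.318, adjusted p = 0.318 and adjusted p = 0.375 with an estimated correlation. For metabolism of foreign compounds and the weaned enterocyte camera gave 1.04e-09 and 0.000249, with adjusted p = 0.318 for each with an estimated correlation.

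Connective tissue, crypt and nerve genes were lower at 7 weeks. Endothelial genes fell in 12 of 12 cases (median -1.8, Cdh5 -2.31 ± 0.28), enteric nervous system genes in 14 of 15 (median -2.61, Ret -2.94 ± 0.19), smooth muscle genes in 9 of 12 (median -1.05, Acta2 -2.19 ± 0.36) and intestinal stem cell genes in 13 of 15 (median -1.43, Axin2 -2.24 ± 0.25). Paneth cell genes fell in 14 of 19 cases with 1 up (median -1.94), with Defa20, Defa21 and Defa22 at -7.1 ± 0.6, -6.6 ± 0.6 and -7.01 ± 0.69, while Lyz1 did not change past the threshold (-1 ± 0.64). Camera gave the fibroblast and proliferation lists adjusted p of 1.04e-09 and 2.74e-06, and these 5 lists 1.66e-05, 6.51e-05, 0.0238, 6.75e-05 and 0.00024. With an estimated correlation the 7 had adjusted p = 0.318, adjusted p = 0.423, adjusted p = 0.318, adjusted p = 0.377, adjusted p = 0.594, adjusted p = 0.318 and adjusted p = 0.452. Suckling enterocyte genes had a median of -0.9, with 8 of 16 down and 2 up, and were not called by camera (adjusted p = 0.078). The fry test called them (adjusted p = 0.00152). The endocytic adaptor Dab2 fell by 5.54 on the log2 scale, Nox4 by 6.15 and the urea cycle enzyme Ass1 by 5.46, and Fcgrt by 1.93, while lactase rose (1.64 ± 0.24).

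Transcripts of pancreas and stomach were present at 2 weeks and nearly absent at 7. All 16 pancreatic acinar genes fell, with a fitted median of -10.5 (-10.09 with genes of at most 3 counts over the group set to a floor of 3), among them the proteases Ctrb1 (-11.77 ± 0.8) and Cela2a (-11.49 ± 0.91) and the lipase Cel (at least 2300-fold lower against the floor). Of the 9 stomach genes 8 fell over all genes (fitted median -8.4, and -8.39 at the floor), among them Muc6 (-8.79 ± 0.83) and Gkn1 (at least 1800-fold lower). Tff2, the trefoil factor of gastric mucus and duodenal glands, went from 747 ± 91.7 CPM (SD, n = 5) to 0 counts, at least 32000-fold lower. The near-identical amylase copies Amy2a2, Amy2a3 and Amy2a4, which carried equal counts, were each at least 3700-fold lower. Fgf15, the ileal hormone that restrains bile acid synthesis, was at 52.9 ± 9.67 CPM at 2 weeks and had 0 counts at 7, at least 2400-fold lower. Fabp6 fell by 10.72 on the log2 scale, and the distal intestine list stood at a fitted median of -2.78 (-2.43 at the floor) and was not called by camera (adjusted p = 0.078). Camera gave the pancreatic and stomach lists adjusted p of 6.61e-06 and 0.00185 (adjusted p = 0.408 for each with an estimated correlation) and the liver list 0.0486 (median -2.84, -2.88 at the floor; adjusted p = 0.318 with an estimated correlation). These floors cover counting error only, and reads of a PCR-amplified library are not independent molecules.

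Ranked by fold, the rises in control pups were led by the drug-metabolising Cyp2c29 (ENSMUSG00000003053, chromosome 19, 39269405 to 39330713; 9.57 ± 0.88, from 1.23 ± 1.09 to 855 ± 239 CPM, SD, n = 5) and Cyp1a1 (ENSMUSG00000032315, chromosome 9, 57687928 to 57703824; 8.71 ± 0.86, from 0.659 ± 0.866 to 229 ± 75.3 CPM). The carboxylesterase Ces1g (7.86 ± 0.4), the glucuronosyltransferase Ugt1a9 (6.71 ± 0.59), the nucleoside transporter Slc28a1 (6.11 ± 0.47) and Hsd17b6 (6.1 ± 0.59) followed beside the antibody genes. Among the falls were Meltf (ENSMUSG00000022780, chromosome 16, 31878810 to 31899020; -13.54 ± 0.85), the gene of the iron-binding surface protein melanotransferrin, Amy2a5 (-11.73 ± 1.45) and the carboxypeptidase Cpb1 (-10.78 ± 1.11). Muc2 rose by 1.07 ± 0.27 and Sis by 2.07 ± 0.72 and Lgr5 fell by 2.31. Reg3b (0.73 ± 0.63), Reg3g (1.45 ± 0.73), Il1b (-0.41 ± 0.36) and Tnf (-0.47 ± 0.49) did not pass. Among sex-linked transcripts Xist fell by 7.72, and the age comparison was also mostly one of libraries with and without that transcript. In all, camera called 22 of 44 lists, 12 up and 10 down. With an estimated correlation 0 held, and fry called 35.

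In periodontitis pups the change with age was as wide, with 11542 genes called by edgeR, 5312 higher and 6230 lower at 7 weeks. Cyp1a1 rose by 12.42 ± 1.07, Cyp2c29 by 11.37 ± 0.96, Slc28a1 by 8.21 ± 0.52, Cyp2b10 by 8.13 ± 0.98 and Jchain by 7.4 ± 0.75 (SE, n = 5 per group). Meltf (-14.81 ± 0.87), Cela2a (at least 6300-fold lower against the floor), Fgf15 (at least 3500-fold lower), Tff2 (at least 23000-fold lower) and Ctrb1 (-12.31 ± 0.77) fell. Metabolism of foreign compounds had a median of 3.18 (23 of 25 up and 1 down), the weaned enterocyte 3.16 (8 of 8 up) and the suckling enterocyte -1.36 (11 of 16 down and 1 up), and all 3 were called by camera (adjusted p = 2.83e-10, 2.06e-05 and 0.00166, with adjusted p = 0.389, adjusted p = 0.389 and adjusted p = 0.514 with an estimated correlation). B cell genes fell in 12 of 17 cases with 1 up (median -1.75, camera adjusted p = 0.0279, and adjusted p = 0.595 with an estimated correlation). Antimicrobial proteins rose in 10 of 17 cases with 3 down (median 1.79, camera adjusted p = 0.03, and adjusted p = 0.573 with an estimated correlation), among them Reg3b (2.99 ± 0.67) and Reg3g (3.4 ± 0.78). Sis rose by 4.33 ± 0.79, Lct by 1.48 ± 0.24, Muc2 by 1.23 ± 0.28 and Igha by 5.39 ± 1.02. Fcgrt fell by 3.93, Lgr5 by 2.03 and Il1b by 0.89. Tnf (-1.06 ± 0.5) and Lyz1 (0.16 ± 0.63) did not pass. Camera called 26 lists, 13 up and 13 down. With an estimated correlation 0 held, and fry called 37. The 2 age comparisons used separate libraries; 9340 genes were called in the same direction in both and 6 in opposite directions. They had a Pearson r of 0.914 across genes, which are not independent replicates.

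**Figure D4:**
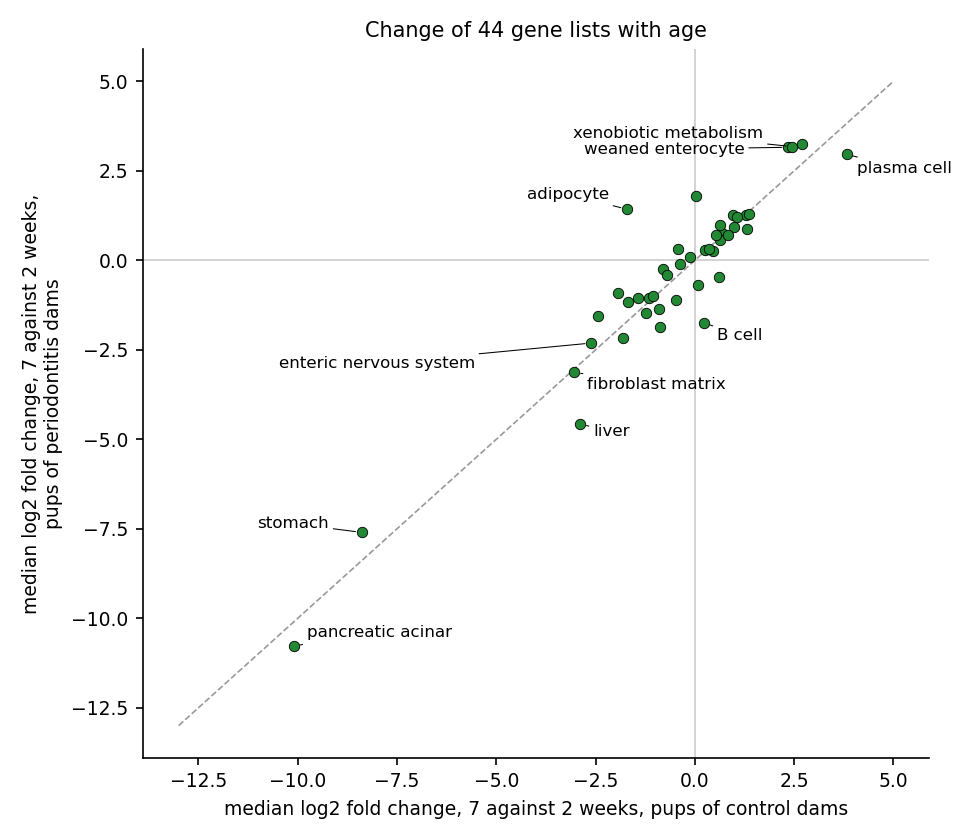
Median log2 fold change between 2 and 7 weeks of 44 gene lists in pups of control dams (horizontal axis) and of dams with periodontitis (vertical axis), 1 point per list; the dashed line marks equal change, and genes with at most 3 counts in a group are set to a floor of 3 counts. Pancreatic acinar genes lie at -10.09 and -10.77, plasma cell genes at 3.83 and 2.96, B cell genes at 0.24 and -1.75 and adipocyte genes at -1.71 and 1.43.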

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

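The maturation test and the test with separate proximal and distal scores were chosen after the result was seen, and the other tests before.

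In 100 groups of 5 libraries, a library lay far from the other 4 in 8 cases by Dixon's ratio, and chance gives about 1 in 20 groups, or 5. Screened were total count, genes with a count, mitochondrial and Apoa4 shares, and the lists camera called in a comparison of dams. Other lists were left out, such as type 2 immunity. Its mean log2 CPM was 3.8 in control library 5 of 2 weeks, against 2.68 to 2.77 in the other controls of that age. Of the 8, 5 were in control library 5 of 2 weeks. It had counts for 20080 genes (23350 to 23574 in the others), a mitochondrial share of 29.4% (3.99 to 4.87), and mean log2 CPM of 7.32 for oxidative phosphorylation (7.72 to 7.85), 1.7 for macrophages and dendritic cells (2.55 to 2.77) and 2.54 for MHC class II (3.45 to 3.67). The other 3 were in periodontitis library 5 of 7 weeks: Apoa4 at 2.12% of counts (4.65 to 5.57), Paneth cell genes at 5.12 (2.71 to 3.18) and proliferation genes at 4.68 (2.62 to 3.08).

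The difference between dams itself differed between 2 and 7 weeks, by a test of that difference, for 4 genes: Retn (7.05), Klf15 (3.16), Scd1 (2.41) and Cfd (7.47). For 13 lists camera called such a difference, with medians of 0.897 for adipocytes, 1.1 for antimicrobial proteins, -2.26 for B cells, -1.87 for liver, -0.776 for macrophages and dendritic cells, -0.829 for MHC class II, 0.241 for oxidative phosphorylation, 0.886 for Paneth cells, 0.508 for proliferation, -0.774 for the suckling enterocyte, -0.326 for T cells, 0.977 for the weaned enterocyte and 0.642 for metabolism of foreign compounds. With an estimated correlation 0 of these 13 stayed. Leaving out 1 of the 20 libraries ended the T cell call in 4 cases (control library 3 and periodontitis libraries 4 and 5 of 7 weeks, periodontitis library 1 of 2 weeks; adjusted p up to 0.123), and its median was -0.133 without that control library and -0.582 without periodontitis library 1 of 7 weeks. It ended the liver call in 3 (control library 4 and periodontitis library 5 of 7 weeks, control library 5 of 2 weeks; up to 0.16) and the Paneth call in 1 (periodontitis library 5 of 7 weeks; median -0.042, 0.0859; 1.56 without control library 1 of 7 weeks). It ended the proliferation call in 8, with adjusted p up to 0.349 and a median of -0.179 without periodontitis library 5 of 7 weeks; the other 7 were control libraries 2, 4 and 5 of 7 weeks and control and periodontitis libraries 4 and 5 of 2 weeks. Without control library 3 of 7 weeks the medians were -0.405 for macrophages and dendritic cells and -0.356 for MHC class II, and without control library 5 of 2 weeks 0.477 for adipocytes, all still called. With the segment covariate they were -0.502, -0.513 and 0.569, with 0.622 for antimicrobial proteins, -0.495 for the suckling enterocyte, -1.23 for liver and 0.286 for metabolism of foreign compounds.

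Suckling enterocyte genes were higher and weaned enterocyte genes lower in periodontitis pups at 2 weeks. The mitochondria-rich control library was not the whole cause, since the suckling median was 0.742 without it. For the stretch of intestine the proximal-minus-distal score (median 0.8) decides nothing, since both lists were lower in periodontitis libraries 3 to 5. With each list as its own covariate the suckling median went from 0.91 to 0.584 and was still called by camera with the preset correlation. An estimated correlation was not tried in that fit, in which edgeR called 0 genes (705 at an unadjusted p under 0.05). Scores of 8 and 6 genes may take away only part of a difference in stretch. The stretch of intestine therefore remains open. A less advanced stage of maturation remains open: across genes the difference between dams ran against the change with age in all 6 ways of giving each contrast 2 of control libraries 1 to 4 of its own, with the genes of both lists left out (Pearson r -0.236 at the highest). The pups' exact ages and litters are not given, so a difference of days, of litter or of the dams' disease could each produce this.

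Scd1, Klf15 and some fat cell genes were higher in periodontitis pups at 7 weeks. The mean log2 CPM of the adipocyte list was 0.48 in periodontitis library 5, below the 0.64 to 1.48 of the controls. The camera call of that list did not hold with an estimated correlation. With the adipocyte genes as a covariate Scd1 went from 1.9 ± 0.28 to 1.64 ± 0.32 and Klf15 from 2.05 ± 0.31 to 2.29 ± 0.37 (SE, n = 5 per group). Both lost their call (edgeR adjusted p = 0.29 and 0.095) as the standard errors were larger and the Scd1 value lower; what else ended the calls was not tested. The adipocyte score, centred within age, ran from -1.06 to -0.226 in control libraries and from 0.844 to 1.9 in periodontitis libraries 1 to 4. It was -1.23 in periodontitis library 5. This covariate nearly parts the groups, so the fit cannot part fat from the dams' condition. In library 5 Scd1 and Klf15 were above all controls with the adipocyte list below them, so fat does not account for them there. For the other libraries, and for Cfd, Retn and Adipoq, fat attached to the tissue remains open.

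B cell genes were lower in periodontitis pups at 7 weeks, with overlap between libraries. Lymphoid follicles caught in some tissue pieces fit, since B cell and follicle scores went together over the 10 libraries, centred within group (Spearman rho 0.612, permutation p = 0.066, and Pearson r 0.689, permutation p = 0.026). Without the 2 farthest libraries the Pearson r was 0.744. The follicle score is a mean over 7 genes outside the B cell list. Both scores could also go together if the pups themselves differed in B cells, so this correlation cannot part the 2 explanations. A difference in B cells between the pups of the 2 kinds of dam remains open.

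The libraries of each comparison were also regrouped in 100 ways, the real one included. For the comparisons of dams both ages were regrouped at once, and for those with age both kinds of dam, each in a shared fit. Where control library 5 was left out, the 2-week libraries alone were regrouped. Regrouping the other libraries as well can widen the shared spread and lower the calls of the other groupings. At 2 weeks 2 groupings called as many genes as the real 5, and the highest other called 31, with control libraries 1 to 4 and periodontitis library 2 on a side. Without control library 5 the real count was 49, 2 groupings called as many, and the highest other called 845 with the same libraries on a side. At 7 weeks 7 groupings called as many as the real 2 and the highest other called 920, so chance is not excluded for that count. For the difference between ages 1 did (4 genes, highest other 1), and so for age in control pups (10739, highest other 0) and in periodontitis pups (11542, highest other 2586). The other groupings for age put both ages into every group, which widens the shared spread. Low counts for most of them were thus largely set beforehand. At 2 weeks and for age in periodontitis pups the highest other groupings kept all but at most 1 library of each side in place, so they still part the real groups for the most part. At 2 weeks, however, they called more genes than the real groups, 31 against 5 and 845 against 49. The second principal component within 2 weeks put periodontitis libraries 1 and 2 at -19 and -20.8, among control libraries 1 to 4 (-38.1 to -18.6). Periodontitis libraries 3 to 5 were at 30.4 to 54.7 and control library 5 at 12.2. The division with the most calls was thus not that of the dams. The grouping with 920 calls put control libraries 1, 3 and 5 with periodontitis libraries 1 and 5. These were the 5 lowest on the first principal component of the 7-week libraries, at -87 to 1.46 against 17 to 55.7 in the others. That component held 38.8% of their variance. What lies behind it was not tested.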

How the results depend on the processing

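The removal of both libraries that stood apart, the removal of mitochondrial genes and the covariates for maturity, adipocyte genes and the proximal and distal scores were chosen after the results were seen. Counts are given for 2 weeks, 7 weeks and the difference between ages in that order, and where they moved the cause was not tested. The counts in the report were 5, 2 and 4. DESeq2 called 599 (41.4% higher, against 60%), 25 (48%, against 100%) and 65 (64.6%, against 100%), and limma-voom with sample quality weights 5170 (49.1%), 10 (40%) and 1166 (66.2%). DESeq2's size factors in edgeR gave 0 (2628 at an unadjusted p under 0.05) at 2 weeks, no robust estimation 17, the covariate for Y-linked transcripts 0 (2028), and the segment covariate 40 at 2 weeks, 3 at 7 weeks and 1 for the difference. Fits to the compared groups alone gave 0 at 2 weeks (2159) and 0 at 7 weeks (383), the maturity covariate 0 (113), the proximal and distal scores as 2 covariates 0 (705) at 2 weeks, the adipocyte covariate 0 (1216), and removal of both libraries 361, 32 and 159. With the replicate block edgeR called 0 genes at 2 weeks (2015), 0 at 7 weeks (500) and 0 for the difference (1139). The numbers do not pair the libraries: the correlation of same-numbered libraries ran from -0.17 to 0.078 at 2 weeks, -0.4 to 0.29 at 7 weeks, -0.14 to 0.086 for age in control pups and -0.024 to 0.15 in periodontitis pups. No filter gave 7 at 2 weeks. Leaving out 1 library gave 0 to 387, 0 to 15 and 1 to 26. The age counts of 10739 and 11542 stayed within 1.5 times under all settings, from 9141 to 14030 and from 10208 to 14122.

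Some log2 fold changes changed sign, and the adipocyte and interferon gamma lists at 7 weeks changed direction in camera without a change in the sign of the median. With the maturity covariate at 2 weeks Il1b was 0.7, Reg3b 0.96, Reg3g 0.78, Lyz1 0.08, Muc2 0.81, Sis 0.06, Jchain 1.16 and Igha 1.47. List medians there were 0.307 for antimicrobial proteins, 0.136 for goblet cells and 0.0955 for oxidative phosphorylation, both called higher (adjusted p = 0.0202 and 0.0374), 0.0825 for Paneth cells, 0.0237 for proliferation, 0.14 for the proximal intestine, 0.144 for the weaned enterocyte and 0.0532 for metabolism of foreign compounds; the covariate is built from 2 of the lists, so it removes what follows them. With the proximal and distal scores as 2 covariates Il1b was 0.21, Muc2 0.33, Igha 0.52, the proliferation median 0.0627 and the oxidative phosphorylation median 0.00235. Without both libraries Il1b was 0.06, Lgr5 0.29 and Lct -0.1 at 2 weeks, Lyz1 -1.03, Sis 0.02, Lct 0.05 and Fcgrt 0.02 at 7 weeks, and Lyz1 -1.1 with age in periodontitis pups. The list medians were then 0.000506 for immediate early genes and 0.0484 for interferon gamma genes at 7 weeks and -0.311 for proliferation in the difference. With sample quality weights Lgr5 was 0.18 and Lct -0.08 at 2 weeks, Lyz1 -0.4 and Lct 0.03 at 7 weeks, and Lyz1 -0.28 with age in periodontitis pups. With the segment covariate Muc2 was 0.07 at 2 weeks, Reg3g -0.36, Muc2 -0.18 and Fcgrt 0.33 at 7 weeks, and Lyz1 -0.12 with age in periodontitis pups. With the adipocyte covariate at 7 weeks Muc2 was -0.08, Lgr5 0.24, Sis 0.46, Jchain 0.53, Igha 0.39 and the adipocyte list 0.127. The cause was not tested.

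Leaving out 1 library, at 2 weeks Il1b ran from -0.27 to 0.06, Muc2 from -0.28 to 0.09, Lgr5 from -0.46 to 0.29 and Lct from -0.09 to 0.19. At 7 weeks Reg3g ran from -0.73 to 1.18, Lyz1 from -1.03 to 0.89, Muc2 from -0.1 to 0.14, Lgr5 from -0.19 to 0.16, Sis from -0.15 to 0.02, Lct from -0.21 to 0.05, Fcgrt from -0.08 to 0.04, Jchain from -0.59 to 0.07 and Igha from -1.66 to 0.23. With age Lyz1 ran from -1.1 to 0.54 in periodontitis pups. T cell genes at 7 weeks were at 0.0816 without control library 3 and proximal genes at 0.00281 without periodontitis library 1. Immediate early genes at 7 weeks ran from -0.441 to -0.000197 and proliferation in the difference from -0.179 to 0.698.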

Other observations

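The correlations below were chosen after the 2-week result was seen.

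Not all periodontitis libraries of 2 weeks took part alike in the run against the change with age. Across genes, the Pearson r of a library's difference from 2 control libraries with the age change measured from 2 others ran, over 6 choices, from -0.13 to 0.064 in library 1 and from -0.091 to 0.11 in library 2. It ran from -0.36 to -0.22 in library 3, from -0.52 to -0.43 in library 4 and from -0.36 to -0.23 in library 5. Control library 5, set against the other controls, had 0.075 to 0.11.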
